A study of Mus musculus with 34 samples.

How the data were processed

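The olfactory epithelium of C57BL/6J mice was profiled by droplet single-cell RNA sequencing with CellPlex sample tags, which mark the cells of each mouse so that several mice can share a capture. Per the labels' protocols, wild-type mice of 6 weeks were housed alone for 7 days and then lived for 7 days with a dish of 8 g of bedding. The dish held 1 mL of water, 1 mL of 0.5% amyl acetate (a fruity odorant), 1 mL of house dust mite (HDM) extract at 2 mg/mL, or 8 g of bedding soiled by mice of another strain. One mouse of each exposure was pooled in a capture, each pool was captured 2 times, and males and females were processed in separate batches. The 16 exposed mice therefore form 4 batches, each with 1 mouse per exposure, and the batch serves as the replicate block. Replicates 1 and 3 are female and replicates 2 and 4 are male. The 2 mice without exposure formed a batch of their own, served only for clustering per the labels' protocols, and are in no comparison.

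The deposited matrices hold UMI counts per gene and cell barcode, without normalization, and the number of barcodes equals the stated cell number in 34 of 34 libraries. Per the submitters' processing notes they were made with Cell Ranger on mm10, with no version given. Gene symbols and identifiers are those of the deposited matrices, and positions come from GENCODE vM21 on GRCm38, matched by identifier. The annotation release behind the deposited matrices is not stated.

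Barcodes with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes were kept, which left 48766 of 61634 barcodes. Scrublet, run in scanpy on each capture, called 100 cells (0.205%) as doublets. That share is far under what pooled captures produce, so the doublet caller did not work here, and mixed clusters were left without a name. The 48666 kept cells were log-normalised, centred within batch on 2000 variable genes without receptor, mitochondrial, ribosomal or sex genes, reduced to 30 principal components and clustered with Leiden at a resolution of 1 on 20 neighbours. The 44 clusters were named by marker lists, which gave 19 named classes. A class name stands for cells that resemble the type by markers, and 13 clusters stayed unnamed. The name was not always the type with the highest marker score. The neutrophil cluster scored 7.26 for neutrophils and 7.74 for myeloid progenitors. The dendritic cluster scored 3.97 against 4.2 for monocytes, and the osteoblast cluster 6.27 against 6.8 for fibroblasts. Clusters 12 and 23, named immediate neuronal precursors, scored 1.18 and 0.96 for these and 1.26 and 1.2 for immature olfactory sensory neurons.

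UMI counts were summed per mouse and class over both captures, so that 1 mouse is 1 replicate. Genes were tested with edgeR quasi-likelihood (TMM scaling, filterByExpr, batch and exposure as terms, all 16 mice in the fit), with Benjamini-Hochberg adjustment within each class and a threshold of 0.05. A class was tested with at least 10 cells in at least 3 mice of each group. Class shares were tested with edgeR on cell counts against all kept cells of the mouse. Mature olfactory sensory neurons (OSNs) were assigned to the receptor with the most UMIs (at least 2, and at least 2 times the next), and receptors with at least 20 cells were tested in the same way. The exposure by sex term compares the difference from water in males with that in females. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over all lists and exposures of a class, and again with an estimated correlation. CPM are counts scaled to the class's UMIs in the mouse, SE is the standard error of a log2 fold change, SD is between mice, and all tests are two-sided. The comparisons share the 4 water mice, so no overlap between exposures was read.

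The tests, the 18 gene lists, the class markers, the rule for naming genes and the alternatives not called added were chosen before the data were examined. In mature OSNs the rule names the 10 rising and 10 falling called genes with the largest change that moved the same way in all 4 batch pairs. Where fewer than 5 genes passed, it names the 5 with the smallest p. In other classes it names 3 rising and 3 falling genes by the same criteria. Of the receptors it names the 3 with the smallest p where 0 pass. It also names called list members, the 2 members with the smallest p of a list that passes, the 5 genes with the smallest p for the exposure by sex term, and S100a5 in every comparison. Receptor and predicted genes are named in the mature OSN lists only if called. One list member that the rule names is not reported here.

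Depth ran from 22702115 to 73577884 UMIs per library and from 46622638 to 73577884 per mouse. Simulated counts had the depth and fitted spread of the data but 1 profile for all mice and no batch differences. Recovery in the real data may therefore be lower. In the simulated counts, edgeR in mature OSNs recovered 68% of 2-fold rises for soiled bedding, 84% for amyl acetate and 68% for HDM, and 88% of 4-fold falls in each. For class shares, a 4-fold change of the B cell class was called in 20 of 20 draws. A 2-fold change of the tuft-type class was called in 13 of 20, with 3 false calls in 340 class tests. In the neutrophil class 1 of 25 genes with a 4-fold rise was recovered for soiled bedding, so only very large differences were detectable there. Of the receptors given a 4-fold change for amyl acetate, 2 of 5 rises and 2 of 5 falls were recovered.

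Alternatives covered the scaling, the test, the low-count filter, the replicate block, the groups in the fit, single captures, the cell filter, doublet calls, the cluster resolution, a marker gate, the receptor rules, the share's denominator and each mouse left out in turn. Added after seeing the data were the removal of cells with a doublet score above 0.25, the interferon-led cluster joined to the sustentacular class, and list tests without each mouse. Other splits of the 8 mice of a comparison were refitted in the same way. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.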

Results

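Single cells of the main olfactory epithelium were profiled in 18 mice to ask what a week of an environmental odour or allergen does to the tissue. Each of the 4 exposure groups (water, soiled bedding, amyl acetate and HDM) held 4 mice, of which 2 were male and 2 female, and 2 male mice had no exposure. The 34 libraries held between 22702115 and 73577884 UMIs. After filtering, an exposed mouse kept between 2222 and 3237 cells, and the median UMIs per kept cell ran from 12022 to 18478.5 over the mice. Xist was at least 479 CPM in every female mouse and at most 0.336 CPM in every male mouse, and Ddx3y was at least 35.01 CPM in males and 0 in females, so 18 of 18 mice matched their labelled sex.

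The tissue held neurons and their precursors, support cells and cells of blood lineages. Mature OSN-like cells, which express Omp, made up 35.1% ± 7.44 (SD, n = 4) of the cells of water mice, sustentacular-like cells 13.4% ± 3.69, immature OSN-like cells 8.24% ± 1.61 and immediate neuronal precursor-like cells 6.84% ± 1.67. Bowman's gland-like cells made up 3.08% ± 1.27, macrophage-like cells 1.30% ± 0.421 and neutrophil-like cells 0.436% ± 0.213. Clusters without a name took 19.3% ± 2.86 of the cells of water mice, 19.2% ± 3.88 after soiled bedding, 20.6% ± 4.14 after amyl acetate and 18.9% ± 3.14 after HDM. RNA of the neuronal gene S100a5 was found outside neurons too, at 25424 CPM in mature OSNs, 1621 CPM in sustentacular cells, 1218 CPM in neutrophils and 1266 CPM in B cells. Most clusters of mature OSNs held mainly the cells of 1 batch, though cluster 16 spanned 3. Before mice were correlated, the mean of the exposure group was subtracted from each gene. Each of the 16 mice then correlated best with a mouse of its own batch over 4686 genes (median r across genes 0.676 within and -0.495 between batches, genes not being independent replicates). A group holds 1 mouse per batch and its deviations cancel out, so values below 0 between batches are partly built in.

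Soiled bedding carries the body odours of other mice, and 11 of the 14 genes called after it were in sustentacular cells, the support cells that detoxify and insulate the epithelium. There, 10 genes fell and 1 rose against water, each the same way in 4 of 4 batch pairs. Ebf1 (ENSMUSG00000057098), a transcription factor of the olfactory neuron lineage on chromosome 11 (44617317 to 45008091, GRCm38), fell from 179 CPM ± 44.6 (SD, n = 4) to 114 ± 47.8, a log2 fold change of -0.72 (SE 0.10, adjusted p = 0.0475). Bhlhe40 (ENSMUSG00000030103), a clock-linked repressor on chromosome 6 (108660629 to 108666925), rose from 129 CPM ± 27.8 to 171 ± 29.9, a log2 fold change of 0.42 (SE 0.07, adjusted p = 0.0480). The largest falls were in Fhl1 at -2.10 (SE 0.37; 0.363 against 1.67 CPM, DESeq2 adjusted p = 0.0642, not passing), Arl14epl at -0.87 (SE 0.15) and Arhgdig at -0.81 (SE 0.14), each with an edgeR adjusted p of 0.0480. The other 6 were Stmn3, Gm1673, Tuba1a, Rnf182, Ckmt1 and Ssbp2, between -0.34 and -0.80. Each of the 10 genes that fell had at least 5 times more CPM in mature OSNs than in sustentacular cells, with Ebf1 at 2082 against 135 CPM. Of the 11 calls in sustentacular cells, 0 were left with the RLE scaling, without the replicate block, in first or second captures alone, and without water replicate 1 or 3 or soiled bedding replicate 1, 2 or 4.

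In neutrophil-like cells S100a5 was lower after soiled bedding, at 306 CPM ± 194 (SD, n = 4) against 7294 ± 2081 (n = 3) in water mice, with a log2 fold change of -4.62 (SE 0.47, adjusted p = 0.000880). Pcp4l1, like S100a5 an abundant OSN transcript, was lower by the same comparison at -3.67 (SE 0.54, adjusted p = 0.0245), and both were lower in 3 of 3 pairs. Neither call was left in a fit of the 2 groups compared, and the Pcp4l1 call also ended without water replicate 4 or soiled bedding replicate 1, 2 or 3. The water group held 43 neutrophil-like cells in all. Coch, the gene of the matrix protein cochlin, was lower in respiratory secretory cells at -6.04 (SE 0.81, adjusted p = 0.00425), yet in 2 of 4 pairs only. Its water level came from replicate 1 at 465 CPM and replicate 4 at 110 CPM, and DESeq2 gave an adjusted p of 1.00. Coch is also a marker and the first leading gene of the ionocyte-type microvillous cluster. Whether such cells or their RNA were mixed into the secretory class, for this or the other exposures, was not tested. These 14 genes came from 105007 tests in 12 classes, of which 6667 had an unadjusted p under 0.05, and DESeq2 called 125. The count was 3 with the RLE scaling and 54 without the replicate block, and it moved by more than 1.5 times without water replicate 2 (266 genes), water replicate 3 (9), or soiled bedding replicates 1 (2), 2 (7), 3 (8) or 4 (8).

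Gene lists showed immune and clock genes higher in sustentacular cells after soiled bedding and neuronal genes lower. All 15 antigen presentation genes were higher, with a median log2 fold change of 0.47, H2-DMb1 at 0.53 (SE 0.14) and Tap1 at 0.47 (SE 0.19), adjusted p = 4.86e-07 and adjusted p = 0.213 with an estimated correlation. Of 16 type I interferon genes 12 were higher, with a median of 0.17, Ifi27 at 0.29 and Ifit2 at -0.68, adjusted p = 0.0105 and adjusted p = 0.441 with an estimated correlation. Of 16 clock genes 13 were higher, with a median of 0.11, Bhlhe40 at 0.42 and Per3 at 0.32, adjusted p = 4.57e-05 and adjusted p = 0.0736 with an estimated correlation. Of the 13 mitochondrial transcripts 12 were higher, with a median of 0.07, mt-Nd2 at 0.12 and mt-Nd1 at 0.09, adjusted p = 0.000234 and adjusted p = 0.441 with an estimated correlation. Of 19 odorant transduction genes 17 were lower, with a median of -0.32 and Gng13 at -0.48, adjusted p = 4.48e-08 and adjusted p = 0.360 with an estimated correlation. Of 11 genes linked to neuronal activity 10 were lower, with a median of -0.39, Calb2 at -0.95 and Lrrc3b at -0.56, adjusted p = 2.86e-06 and adjusted p = 0.108 with an estimated correlation. Of 22 axon guidance genes 18 were lower, with a median of -0.15, Ncam1 at -0.54 and Epha7 at -0.55, adjusted p = 0.000125 and adjusted p = 0.239 with an estimated correlation. Of 14 neurogenesis genes 9 were lower, with a median of -0.43, Lhx2 at -0.60 and Dpysl3 at -0.54, adjusted p = 0.000548 and adjusted p = 0.0736 with an estimated correlation. Adjusted over the list alone, of the lists that passed, 6 activity-linked, 5 transduction, 5 neurogenesis, 3 axon guidance, 3 clock and 1 antigen presentation gene passed, while over all genes Bhlhe40 alone did. The interferon call in these cells ended without water replicate 1 or soiled bedding replicate 3 (highest adjusted p = 0.0838, without water 1).

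Immature OSNs, the neurons still growing their axons, had lower levels of guidance and transduction genes after soiled bedding. Of 21 axon guidance genes 18 were lower, with a median of -0.09, Tenm4 at -0.33 (SE 0.09) and Kirrel2, an adhesion gene that follows neuronal activity, at -0.64 (SE 0.17), adjusted p = 7.93e-05 and adjusted p = 0.0378 with an estimated correlation. Of 19 xenobiotic metabolism genes 15 were lower, with a median of -0.20, Gstm1 at -0.24 and Sult1d1 at -0.22, adjusted p = 6.67e-05 and adjusted p = 0.0378 with an estimated correlation. Gstm1 is also a leading gene of a sustentacular cluster, and RNA of the sustentacular gene Cyp2g1 was found in 51.8% of immature OSNs (56.6 CPM). Whether RNA of support cells has a part in the change of this list, after this or the other exposures, was not tested. RNA of Omp and S100a5 was found in 73.0% and 90.0% of immature OSNs (435 and 698 CPM, against 5498 and 25424 CPM in mature OSNs). Whether RNA of mature OSNs has a part in the lower guidance, transduction and activity-linked lists of immature OSNs, after any exposure, was not tested either. Of 19 odorant transduction genes 18 were lower, with a median of -0.28 and Gng13 at -0.23, adjusted p = 3.12e-10 and adjusted p = 0.381 with an estimated correlation. All 13 mitochondrial transcripts were lower, with a median of -0.09, mt-Nd4l at -0.19 and mt-Nd5 at -0.20, adjusted p = 0.00151 and adjusted p = 0.491 with an estimated correlation. Of 15 unfolded protein response genes 12 were higher, with a median of 0.07, Pdia6 at 0.16 and Xbp1 at 0.14, adjusted p = 0.0152 and adjusted p = 0.443 with an estimated correlation. Of 12 neurogenesis genes 10 were higher, with a median of 0.10, Sox11 at 0.10 and Insm1 at 0.16, adjusted p = 0.0399 and adjusted p = 0.443 with an estimated correlation. The activity-linked list did not pass (adjusted p = 0.0611). When adjusted over the list alone, 2 axon guidance genes and 1 activity-linked gene passed, and over all genes edgeR called 0 members of these lists. The transduction call ended without water replicate 4 (adjusted p = 0.0569), and that on mitochondrial transcripts without water 4 or soiled bedding 4 (highest 0.136, without soiled bedding 4). Water replicate 4 had 131 immature OSNs, or 5.90% of its cells (8.57% to 9.52% in the other water mice), and 70.0% of its barcodes passed the cell filter (80.5% to 83.8% in the others). The call on the unfolded protein response ended without water 1, 2 or 4 or soiled bedding 2 or 4, and that on neurogenesis without water 4 or soiled bedding 1, 2 or 4 (highest 0.199 and 0.527, each without water 4).

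In mature OSNs, the cells that face the odour, no single gene passed with edgeR after soiled bedding. It called 0 of 13314 genes, 512 had an unadjusted p under 0.05, and DESeq2 called 17, all of them receptor genes. Over the 4701 genes above 32 CPM, the central 90% of log2 fold changes lay between -0.08 and 0.08, with a median SE of 0.04, and over all 12647 genes other than receptors between -0.24 and 0.22. S100a5, a calcium-binding protein whose level follows neuronal activity, stood at 25884 CPM ± 3960 (SD, n = 4) against 25367 ± 4556 in water mice, a log2 fold change of 0.03 (SE 0.09), higher in 2 of 4 pairs. Outside receptor and predicted genes, the smallest p values belonged to Pcdhb19 at 0.45 (SE 0.09), Elmo2 at 0.16 (SE 0.04), Prkci at -0.35 (SE 0.08), Smim6 at 0.60 (SE 0.14) and Trmt1l at -0.15 (SE 0.04), none of which passed (adjusted p = 1.00). Among the lists, 10 of 12 type I interferon genes were higher, with a median of 0.29, adjusted p = 8.02e-05 and adjusted p = 0.778 with an estimated correlation. Rtp4, an interferon-induced receptor chaperone, stood at 1.10 CPM ± 0.556 against 0.242 ± 0.122 and Bst2 at 3.99 ± 2.05 against 2.18 ± 1.09. Both were higher in 4 of 4 pairs, at log2 fold changes of 2.29 (SE 0.73) and 0.82 (SE 0.29), and neither passed alone. Of the 13 mitochondrial transcripts 12 were lower, with a median of -0.04, mt-Co1 at -0.05 and mt-Nd4l at -0.06, adjusted p = 0.0194 and adjusted p = 0.899 with an estimated correlation, and that call ended without water replicate 1 or 4 or soiled bedding replicate 1, 2 or 4 (highest adjusted p = 0.485, without water 4). Adjusted over the list alone, 0 genes of either list passed.

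No cell class passed the test of its share after soiled bedding. Mature OSNs were 35.3% ± 7.41 (SD, n = 4) of the cells, against 35.1% ± 7.44. The B cell class was 0.580% ± 0.548 against 0.227% ± 0.156, a fold of 2.38 (SE 0.51 on the log2 scale) in 3 of 4 pairs, which did not pass (adjusted p = 0.427). edgeR called 0 of 19 classes, and 1 had an unadjusted p under 0.05. Without soiled bedding replicate 2 the B cell class alone passed.

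Amyl acetate is a single odorant, and its mice held more cells of the B and erythroid lineages. The B cell class rose from 0.227% ± 0.156 (SD, n = 4) of the cells to 0.974% ± 0.460, a log2 fold change of 2.11 (SE 0.47, adjusted p = 0.00286). The erythroid class rose from 0.0435% ± 0.0637 to 0.320% ± 0.215, a log2 fold change of 2.86 (SE 0.71, adjusted p = 0.00423). Both were higher in 4 of 4 pairs and rest on 106 against 22 B class cells and 34 against 4 erythroid cells. The neutrophil class stood at 0.888% ± 0.418 against 0.436% ± 0.213, a log2 fold change of 1.02 (SE 0.36) in 4 of 4 pairs, and did not pass (adjusted p = 0.0579). T, NK or innate lymphoid cells had a log2 fold change of 0.75 (SE 0.51) and dendritic cells one of 0.40 (SE 0.35), and neither passed. Mature OSNs were 34.9% ± 6.34 of the cells. edgeR called 2 of the 19 classes. Without the replicate block 0 classes passed (B cell 2.09 and erythroid 2.82, adjusted p = 0.243), and without water replicate 4 the erythroid call ended (adjusted p = 0.0628). Without water replicate 2 or amyl acetate replicate 3 the neutrophil class passed as well, which makes 3 classes.

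**Figure D1:**
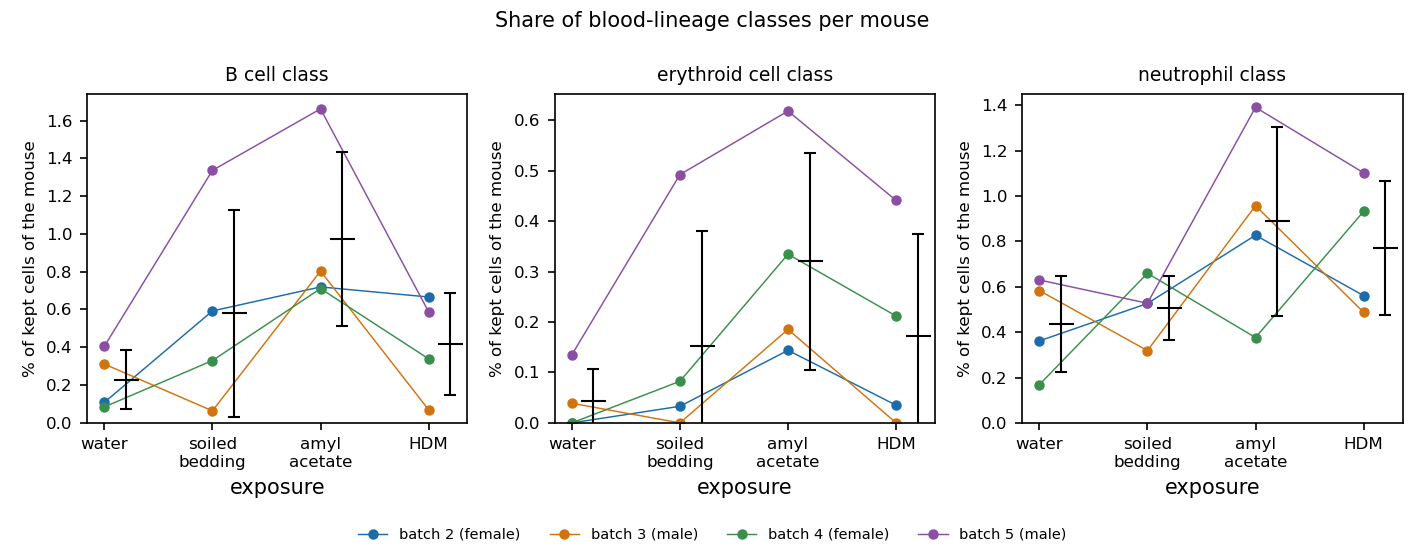
Percent of a mouse's kept cells in the B cell, erythroid and neutrophil classes (vertical axes, each from 0) for the 4 exposure groups (horizontal axes). Each point is 1 mouse, a thin line joins the mice of 1 batch, and the black bar is the mean with its SD over 4 mice. The B cell class has a mean of 0.974% after amyl acetate and 0.227% with water.

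Bowman's glands, which secrete the mucus over the epithelium, had 9 genes called higher after amyl acetate, and 2 of them were higher in 4 of 4 pairs. Gkn3 (ENSMUSG00000030048), a gastrokine on chromosome 6 (87383256 to 87388935), rose from 178 CPM ± 88.0 (SD, n = 4) to 461 ± 231, a log2 fold change of 1.38 (SE 0.22, adjusted p = 0.0208, DESeq2 adjusted p = 0.00396). C2 (ENSMUSG00000024371), a complement protease on chromosome 17 (34862604 to 34898265), rose from 0.537 CPM ± 0.629 to 5.33 ± 4.63, a log2 fold change of 3.15 (SE 0.49, adjusted p = 0.0140, DESeq2 adjusted p = 0.0172). Neither passed without the replicate block or without water replicate 1, 3 or 4 or amyl acetate replicate 1 or 4. Gkn3 also stood at 352 CPM ± 153 after soiled bedding and 499 ± 292 after HDM, and C2 at 1.95 ± 1.51 and 3.42 ± 3.21. For these exposures edgeR called 0 genes of this class. The values do not show the 2 rises to be particular to amyl acetate. The other 7 were genes of secreted carriers and their neighbours (Obp1a, Obp1b, Mup5, Lcn11, Gm14743, Gm14744 and 5430402E10Rik), with log2 fold changes between 6.39 and 9.25. They came from 1 mouse, amyl acetate replicate 1, in which Obp1a reached 11521 CPM and Mup5 4895 CPM. Obp1a was 0 CPM in the other 3 amyl acetate mice and 45.7 CPM in water replicate 1, and DESeq2 gave each of the 7 an adjusted p of 1.00. The same 7 genes also led an unnamed cluster of 343 neurons, mainly of batch 2, with cells in each exposure group.

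In neutrophil-like cells S100a5 was lower after amyl acetate at -4.38 (SE 0.50, adjusted p = 0.00331) and Pcp4l1 at -3.97 (SE 0.56, adjusted p = 0.0174), each in 3 of 3 pairs, and neither passed in a fit of the 2 groups compared or without amyl acetate replicate 4. The Pcp4l1 call also ended without water replicate 4 or amyl acetate replicate 1. Coch was lower in respiratory secretory cells at -4.65 (SE 0.74, adjusted p = 0.0410), in 2 of 4 pairs, and did not pass with DESeq2 (adjusted p = 1.00). Over the 12 classes edgeR called 12 genes, 6033 tests had an unadjusted p under 0.05, and DESeq2 called 121. The count was 4 without the replicate block, and it moved by more than 1.5 times without water replicate 1 (45 genes), water replicate 2 (47), or amyl acetate replicates 1 (5), 2 (22) or 3 (19).

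Interferon and antigen presentation genes were higher in sustentacular cells of amyl acetate mice. Of 16 type I interferon genes 15 were higher, with a median of 0.44, Ifi27 at 0.47 (SE 0.10) and Isg15 at 0.52 (SE 0.14), adjusted p = 1.72e-13 and adjusted p = 0.0736 with an estimated correlation. All 15 antigen presentation genes were higher, with a median of 0.42, H2-K1 at 0.42 (SE 0.11) and H2-D1 at 0.28 (SE 0.09), adjusted p = 3.66e-12 and adjusted p = 0.108 with an estimated correlation. Of 16 clock genes 11 were higher, with a median of 0.08, Bhlhe40 at 0.28 and Per3 at 0.21, adjusted p = 0.00483 and adjusted p = 0.108 with an estimated correlation. Of 13 mitochondrial transcripts 11 were higher, with a median of 0.04 and mt-Co1 and mt-Nd1 at 0.05 each, adjusted p = 0.0482 and adjusted p = 0.645 with an estimated correlation. Of 14 neurogenesis genes 10 were lower, with a median of -0.27, Sox11 at -0.77 and Gng8 at -0.57, adjusted p = 0.000224 and adjusted p = 0.0736 with an estimated correlation. Of 22 axon guidance genes 18 were lower, with a median of -0.13, Nrp1 at -0.32 and Epha5 at 0.23, adjusted p = 0.0161 and adjusted p = 0.455 with an estimated correlation. Of 12 heat shock genes 9 were lower, with a median of -0.09, Hspa8 at -0.18 and Hspd1 at -0.12, adjusted p = 0.00289 and adjusted p = 0.441 with an estimated correlation. The odorant transduction list (adjusted p = 0.552) and the activity-linked list (adjusted p = 0.0739) did not pass here. When adjusted over the list alone, of the lists that passed, 9 interferon genes, 3 antigen presentation genes, 1 clock gene and 1 neurogenesis gene passed, and over all genes edgeR called 0. The clock call ended without water replicate 3 (adjusted p = 0.0597) and the axon guidance call without water 1 or 3 or amyl acetate 3 or 4 (highest 0.250, without water 3). The heat shock call ended without water 1 or 2 or amyl acetate 1 or 2 (highest 0.161, without amyl acetate 1), and the mitochondrial call without water 1, 2 or 3 or amyl acetate 4 (highest 0.838, without amyl acetate 4).

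**Figure D2:**
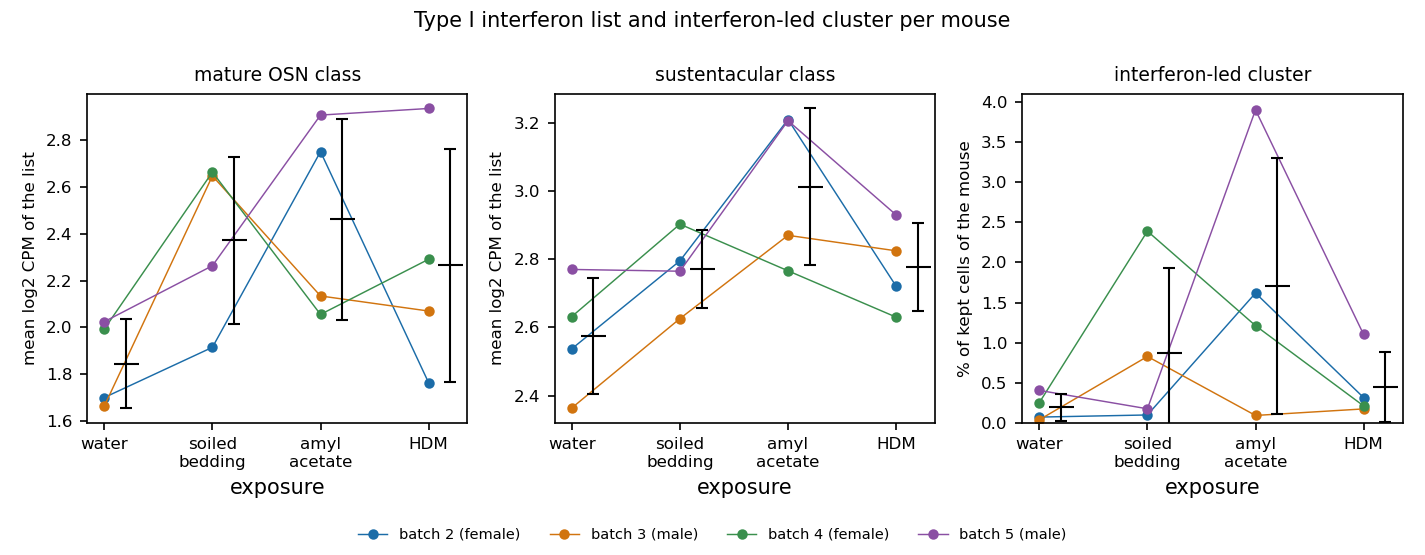
Mean log2 CPM of the type I interferon list in the mature OSN and sustentacular classes, and percent of a mouse's kept cells in the cluster led by interferon genes (vertical axes), for the 4 exposure groups (horizontal axes). Each point is 1 mouse, a thin line joins the mice of 1 batch, and the black bar is the mean with its SD over 4 mice. The cluster has a mean of 1.71% after amyl acetate and 0.192% with water.

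Immature OSNs of amyl acetate mice had lower levels of genes linked to neuronal activity, and a part of mature OSN RNA in this was not tested. Of 11 such genes 10 were lower, with a median of -0.36, Kirrel2 at -0.66 (SE 0.18) and Lrrc3b at -0.55 (SE 0.21), adjusted p = 8.29e-06 and adjusted p = 0.0378 with an estimated correlation. Of 21 axon guidance genes, a list that also holds Kirrel2, 18 were lower, with a median of -0.09 and Epha5 at -0.81, adjusted p = 0.000188 and adjusted p = 0.0378 with an estimated correlation. Of 19 odorant transduction genes 18 were lower, with a median of -0.21 and Ano2 at -0.40, adjusted p = 3.6e-08 and adjusted p = 0.443 with an estimated correlation. Of 19 xenobiotic metabolism genes 15 were lower, with a median of -0.13, Nqo1 at -1.54 and Gstm1 at -0.14, adjusted p = 0.0377 and adjusted p = 0.316 with an estimated correlation. All 13 mitochondrial transcripts were lower, with a median of -0.06, mt-Nd6 at -0.25 and mt-Nd4l at -0.10, adjusted p = 0.0313 and adjusted p = 0.628 with an estimated correlation. Of these lists, 2 axon guidance genes and 1 activity-linked gene passed when adjusted over the list alone, and over all genes edgeR called 0. The transduction call ended without water replicate 4 (adjusted p = 0.567), the mouse with 131 immature OSNs, and the xenobiotic call without water 3 or 4 or amyl acetate 3 or 4 (highest 0.426, without water 4). The mitochondrial call ended without amyl acetate 1 or 4 (highest 0.356, without amyl acetate 4).

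In mature OSNs after amyl acetate, interferon genes were higher as a list and 0 single genes passed with edgeR over all genes. Of 12 type I interferon genes 10 were higher, with a median of 0.50, adjusted p = 1.52e-07 and adjusted p = 0.778 with an estimated correlation. Rtp4 stood at 1.72 CPM ± 1.2 (SD, n = 4) against 0.242 ± 0.122 in water mice and Bst2 at 3.95 ± 1.49 against 2.18 ± 1.09, at log2 fold changes of 2.78 (SE 0.72) and 0.90 (SE 0.30), each higher in 4 of 4 pairs. Of the more abundant members, Ifi27 stood at 136 CPM against 89.2, Ifit1 at 54.9 against 51.6 and Ifit2 at 18.9 against 19.3. Of the 13 mitochondrial transcripts 11 were lower, with a median of -0.03, mt-Co2 at -0.04 and mt-Cytb at -0.05, adjusted p = 0.0469 and adjusted p = 0.899 with an estimated correlation, a call that ended without water replicate 1 or 4 or amyl acetate replicate 3 or 4 (highest adjusted p = 0.879, without amyl acetate 4). When adjusted over the list alone, 3 interferon genes passed. Over all 13314 genes edgeR called 0, 526 had an unadjusted p under 0.05, and DESeq2 called 19, all of them receptor genes. S100a5 stood at 27455 CPM ± 6770 against 25367 ± 4556, a log2 fold change of 0.10 (SE 0.09), higher in 2 of 4 pairs. Receptor and predicted genes aside, the smallest p values belonged to Rsrc1 at -0.11 (SE 0.02), Safb at -0.12 (SE 0.03), Nptxr at -0.17 (SE 0.04), Pdcd11 at 0.26 (SE 0.06) and Igip at -0.41 (SE 0.10), none of which passed (adjusted p = 1.00). Over the 4701 genes above 32 CPM, the central 90% of log2 fold changes lay between -0.08 and 0.08, and over all 12647 genes other than receptors between -0.23 and 0.24.

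HDM extract is a common airway allergen, and after it some neuronal genes were lower in sustentacular and neutrophil-like cells while the type 2 immunity list did not pass in mature OSNs or sustentacular cells, the classes in which it was tested. In sustentacular cells Ebf1 fell from 179 CPM ± 44.6 (SD, n = 4) to 114 ± 42.4, a log2 fold change of -0.69 (SE 0.10, adjusted p = 0.0475). Selenom (ENSMUSG00000075702), a selenoprotein on chromosome 11 (3514684 to 3517351), fell from 57.9 CPM ± 17.8 to 32.9 ± 12.6, a log2 fold change of -0.84 (SE 0.12, adjusted p = 0.0475). Both were lower in 4 of 4 pairs, and Selenom was 652 CPM in mature OSNs against 45.2 in sustentacular cells. Neither passed with the RLE scaling, without the replicate block, in first captures alone or without any 1 mouse other than water replicate 2. In neutrophil-like cells S100a5 at -4.52 (SE 0.46), Pcp4l1 at -3.88 (SE 0.58), Omp at -5.09 (SE 0.80), Stoml3 at -5.23 (SE 0.87), Map1lc3a at -2.38 (SE 0.42) and Ctxn3 at -4.86 (SE 0.86) were lower in 3 of 3 pairs, with adjusted p values from 0.000890 to 0.0488, and 0 of the 6 passed in a fit of the 2 groups compared. Of these 6, S100a5 alone passed without water replicate 1 or 4 or HDM replicate 2, and S100a5 and Pcp4l1 alone without HDM replicate 3 or 4. Without water replicate 2 the Map1lc3a call ended, and without HDM replicate 1 all 6 were kept. Omp, the marker of mature OSNs, stood at 62.2 CPM ± 53.6 (n = 4) against 1482 ± 1028 in water mice (n = 3), and at 5498 CPM in mature OSNs. Coch was lower in respiratory secretory cells at -4.44 (SE 0.71, adjusted p = 0.0488), in 2 of 4 pairs, and did not pass with DESeq2 (adjusted p = 1.00). edgeR called 9 genes over the 12 classes, 6539 tests had an unadjusted p under 0.05, and DESeq2 called 158. The count was 37 without the replicate block, and it moved by more than 1.5 times without water replicate 2 (340 genes), water replicate 4 (4), or HDM replicates 1 (62), 3 (2) or 4 (5).

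The lists in sustentacular cells after HDM were led by neuronal genes. Of 19 odorant transduction genes 18 were lower, with a median of -0.42 and Gng13 at -0.58 (SE 0.14), adjusted p = 6.97e-12 and adjusted p = 0.214 with an estimated correlation. Of 22 axon guidance genes 20 were lower, with a median of -0.17, Epha7 at -0.81 and Ncam1 at -0.62, adjusted p = 2.26e-07 and adjusted p = 0.108 with an estimated correlation. Of 11 activity-linked genes 9 were lower, with a median of -0.45, S100a5 at -0.69 and Pcp4l1 at -0.16, adjusted p = 1.87e-06 and adjusted p = 0.108 with an estimated correlation. Of 14 neurogenesis genes 10 were lower, with a median of -0.45, Lhx2 at -0.44 and Dpysl3 at -0.45, adjusted p = 0.00469 and adjusted p = 0.108 with an estimated correlation. Of 16 clock genes 11 were higher, with a median of 0.07, Bhlhe40 at 0.28 and Nr1d2 at 0.26, adjusted p = 0.00885 and adjusted p = 0.120 with an estimated correlation. Of 15 antigen presentation genes 12 were higher, with a median of 0.14, H2-DMb1 at 0.37 and H2-D1 at 0.19, adjusted p = 0.0150 and adjusted p = 0.513 with an estimated correlation. Of 16 type I interferon genes 14 were higher, with a median of 0.12, Oasl2 at 0.48 and Ifit2 at -0.86, adjusted p = 0.0176 and adjusted p = 0.455 with an estimated correlation. Of 14 odorant binding and mucus genes 12 were higher, with a median of 0.28, Bpifb4 at 1.75 and Pigr at 0.87, adjusted p = 0.0323 and adjusted p = 0.389 with an estimated correlation. Of 24 immediate early genes 17 were higher, with a median of 0.06 and a mean of the opposite sign at -0.03, Klf2 at 0.37 and Fos at 0.16, adjusted p = 0.0143 and adjusted p = 0.594 with an estimated correlation. Adjusted over the list alone, of the lists that passed, 12 transduction, 10 axon guidance, 8 activity-linked, 7 immediate early, 6 neurogenesis, 2 clock and 2 interferon genes passed, and over all genes edgeR called 0. The interferon call ended without water replicate 1 or 2 or HDM replicate 2 or 4 (highest adjusted p = 0.234, without water 1), and the antigen presentation call without water 2 or 3 or HDM 2 (highest 0.0923, without water 3). The mucus call ended without water 1, 2 or 3 or HDM 1 or 2 (highest 0.191, without water 3), and the immediate early call without water 3 or 4 or HDM 2, 3 or 4 (highest 0.515, without water 4).

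**Figure D3:**
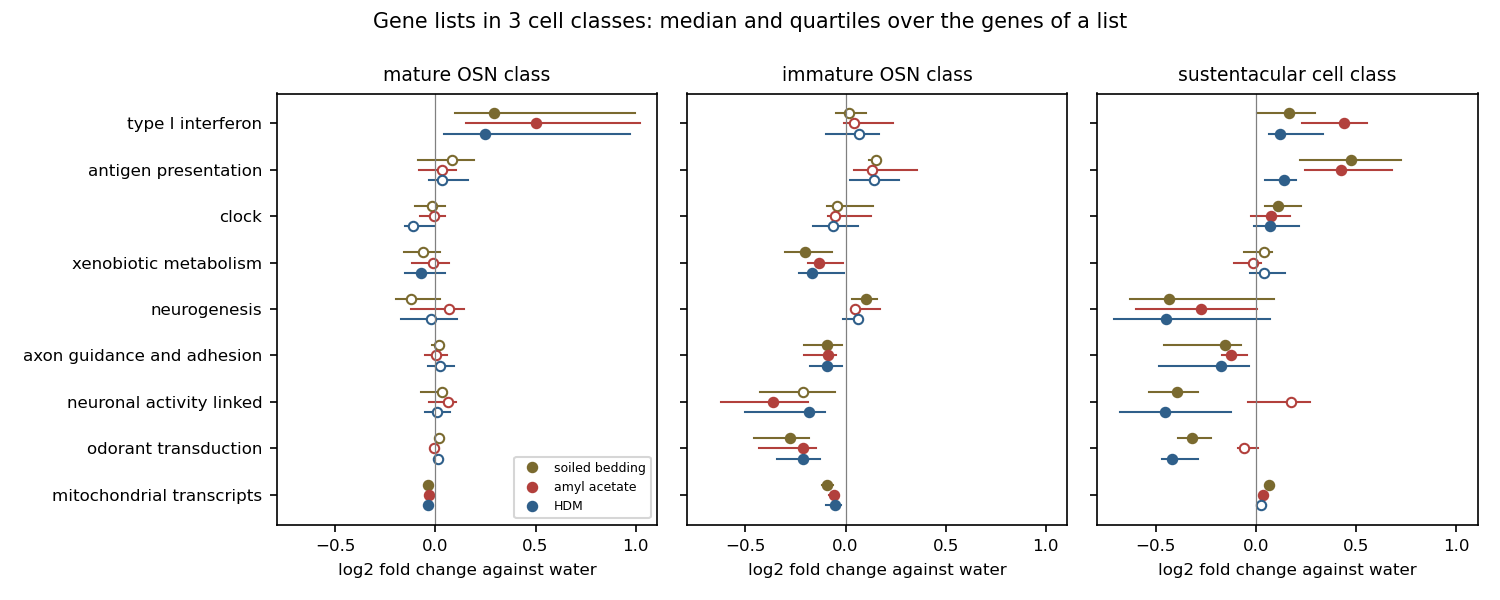
Median (point) and quartiles (line) of the log2 fold change against water (horizontal axes) over the genes of 9 lists (vertical axis), in mature OSNs, immature OSNs and sustentacular cells, with 1 colour per exposure. A filled point has an adjusted p under 0.05 at the preset correlation. Odorant transduction genes have medians of -0.28, -0.21 and -0.22 in immature OSNs after soiled bedding, amyl acetate and HDM.

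Immature OSNs after HDM had lower guidance, transduction and activity-linked genes, and a part of mature OSN RNA in this was not tested. Of 21 axon guidance genes 17 were lower, with a median of -0.09, Epha5 at -0.80 (SE 0.24) and Slit1 at -0.45 (SE 0.15), adjusted p = 0.000276 and adjusted p = 0.0378 with an estimated correlation. Of 19 odorant transduction genes 18 were lower, with a median of -0.22, Pde4a at -0.29 and Slc12a2 at -0.13, adjusted p = 7e-07 and adjusted p = 0.443 with an estimated correlation. Of 11 activity-linked genes 9 were lower, with a median of -0.18, Kirrel2 at -0.52 and Sphkap at 2.67, adjusted p = 0.0268 and adjusted p = 0.381 with an estimated correlation. Of 19 xenobiotic metabolism genes 15 were lower, with a median of -0.17, Gstm1 at -0.17 and Sult1d1 at -0.18, adjusted p = 0.0137 and adjusted p = 0.181 with an estimated correlation. All 13 mitochondrial transcripts were lower, with a median of -0.06, mt-Nd6 at -0.35 and mt-Nd5 at -0.15, adjusted p = 0.0268 and adjusted p = 0.628 with an estimated correlation. When adjusted over the list alone, and over all genes, edgeR called 0 members of these lists. Without water replicate 4, the mouse with 131 immature OSNs, the calls on transduction (adjusted p = 0.926), activity (0.335) and xenobiotic metabolism (0.216) ended. The activity call ended also without HDM 1 or 4, and the mitochondrial call without HDM 4 (0.453).

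Mature OSNs after HDM had higher interferon genes as a list and 0 single genes past the threshold. Of 12 type I interferon genes 11 were higher, with a median of 0.25, adjusted p = 0.00831 and adjusted p = 0.896 with an estimated correlation. Bst2 stood at 3.86 CPM ± 1.90 (SD, n = 4) against 2.18 ± 1.09 and Usp18 at 0.780 ± 0.642 against 0.261 ± 0.0770, at log2 fold changes of 0.81 (SE 0.29) and 1.46 (SE 0.69), each higher in 4 of 4 pairs. Usp18 rests on few UMIs. Of the more abundant members, Ifi27 stood at 117 CPM against 89.2, Ifit1 at 52.4 against 51.6 and Ifit2 at 19.4 against 19.3. The interferon call ended without water replicate 4 or HDM replicate 4 (highest adjusted p = 0.290, without HDM 4). Of 26 xenobiotic metabolism genes 18 were lower, with a median of -0.07, Cbr2 at -0.14 and Por at -0.08, adjusted p = 0.0469 and adjusted p = 0.778 with an estimated correlation, a call that ended without water replicate 1 or 4 or HDM replicate 2 or 4 (highest adjusted p = 0.525, without HDM 4). Of the 13 mitochondrial transcripts 12 were lower, with a median of -0.04, mt-Nd2 at -0.08 and mt-Co3 at -0.07, adjusted p = 0.0193 and adjusted p = 0.899 with an estimated correlation, a call that ended without water replicate 1 or 4 or HDM replicate 1, 2 or 4 (highest adjusted p = 0.485, without water 4). Adjusted over the list alone, 0 genes of these lists passed. edgeR called 0 of 13314 genes, 692 had an unadjusted p under 0.05, and DESeq2 called 12, all of them receptor genes. S100a5 stood at 25701 CPM ± 5390 against 25367 ± 4556, a log2 fold change of 0.01 (SE 0.09), higher in 3 of 4 pairs. Of the genes other than receptor and predicted genes, the smallest p values belonged to Ctbp1, a corepressor, at -0.12 (SE 0.02, adjusted p = 0.896), Dmxl1 at -0.16 (SE 0.03), Jak2 at -0.23 (SE 0.05), Cntfr at 1.34 (SE 0.31) and Igip at -0.42 (SE 0.10), none of which passed.

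No cell class passed the test of its share after HDM. edgeR called 0 of 19 classes, and 3 had an unadjusted p under 0.05. These were the tuft-type microvillous class at 0.491% ± 0.284 (SD, n = 4) against 0.864% ± 0.705 with water, the erythroid class at 0.172% ± 0.202 against 0.0435% ± 0.0637 and the neutrophil class at 0.771% ± 0.295 against 0.436% ± 0.213, each with an adjusted p of 0.273. Dendritic cells, a main target of allergens, were 0.736% ± 0.291 against 0.509% ± 0.274. Mature OSNs were 34.4% ± 6.07 of the cells.

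Lists were tested in mature OSNs, immature OSNs and sustentacular cells, and in no immune class. Inflammatory cytokines and basal cell activation passed in none of these 3 classes for any exposure. Type 2 immunity did not pass in mature OSNs or sustentacular cells, with 4 and 5 of its 20 genes tested, nor did trace amine receptors in mature OSNs or the guanylate cyclase D system in sustentacular cells, of which 3 genes were tested. Of those 3, Car2 at 2.84 (SE 0.91) and Gucy2d at 3.23 (SE 1.26) passed for HDM when adjusted over the list alone, while the list had an adjusted p of 0.0808. Of 147 list tests 47 passed at the preset correlation (7 in mature OSNs, 16 in immature OSNs and 24 in sustentacular cells). By exposure these were 16, 14 and 17 for soiled bedding, amyl acetate and HDM. Other splits of the 8 mice of a comparison passed medians of 10, 11 and 10 lists. A pass at the preset correlation alone is therefore weak evidence of an effect of the exposure. With an estimated correlation 5 of the 147 tests passed, all in immature OSNs. These were axon guidance for each exposure, activity-linked genes for amyl acetate and xenobiotic metabolism for soiled bedding.

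Receptor choice asks whether an odour changes how many neurons carry a given receptor. The 14723 OSNs of the 16 mice with an assigned receptor (635 to 1374 per mouse) carried 950 receptors, and 208 had enough cells to test, with a median of 34 cells. edgeR called 0 for each exposure, with 7, 13 and 6 receptors at an unadjusted p under 0.05 for soiled bedding, amyl acetate and HDM, and DESeq2 called 0. After soiled bedding the smallest p values belonged to Olfr110 with 10 cells against 1 in water mice (log2 fold change 2.63, SE 1.11), Olfr286 with 22 against 7 (1.36, SE 0.61) and Olfr1260 with 28 against 10 (1.20, SE 0.54), adjusted p = 0.966 each. After amyl acetate Olfr742 had 5 cells against 20 (-2.07, SE 0.67, lower in 4 of 4 pairs, adjusted p = 0.382), Olfr110 13 against 1 (3.06, SE 1.05, adjusted p = 0.382) and Olfr775 16 against 3 (2.10, SE 0.79, adjusted p = 0.533). After HDM Olfr775 had 19 cells against 3 (2.40, SE 0.76, adjusted p = 0.328), Olfr166 38 against 15 (1.23, SE 0.45, adjusted p = 0.646) and Olfr1247 26 against 9 (1.38, SE 0.57, adjusted p = 0.921). Olfr110, Olfr775, Olfr166 and Olfr1247 were higher in 4 of 4 pairs in these comparisons and did not pass.

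Whether males and females differ in their answer was tested in mature OSNs with 2 mice per sex and exposure. edgeR called 0 of 13314 genes for each exposure, with 429, 499 and 485 at an unadjusted p under 0.05 for soiled bedding, amyl acetate and HDM, and DESeq2 called 13, 20 and 20. S100a5 differed between the sexes by log2 values of -0.00 for soiled bedding, 0.05 for amyl acetate and -0.05 for HDM (SE 0.21 each). The smallest p values all belonged to receptor genes, each but Olfr318 with a group at or near 0. For soiled bedding, Olfr318 was 5.55 CPM against 12.7 in males and 19.1 against 9.98 in females (exposed against water), beside Olfr1154, Olfr816, Olfr1274-ps and Olfr665 (adjusted p = 1.00). For amyl acetate, Olfr318 was 4.60 CPM in males and 17.2 in females, beside Olfr1044, Olfr1130, Olfr1325 and Olfr1014 (adjusted p = 1.00). For HDM, Olfr1154 was 0 against 3.80 CPM in males and 3.85 against 0 in females, beside Olfr1044, Olfr826, Olfr816 and Olfr813, with adjusted p values from 0.548 to 0.874. On simulated data a 4-fold difference between the sexes was recovered in 54.2% to 75% of genes.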

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

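The tests of leukocyte RNA and of free RNA in sustentacular cells after HDM, and the other splits for the interferon list, were chosen before their results were seen; the allowance for spread in these leukocyte-RNA and free-RNA tests was added after the values were seen, and all remaining tests of this part were chosen after the result they examine.

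Of 188 groups of 4 mice that were screened, 39 held a mouse far from the other 3. The critical value gives about 1 in 20 by chance in independent, normally spread groups, which these are not. Each group holds 1 mouse per batch, so differences between batches enter the screen. The genes screened were those already called, and some were absent from most mice. Of the 39 groups, 28 are the 7 secretory genes of Bowman's glands in replicate 1 of each exposure, the batch 2 mice. In CPM for water, soiled bedding, amyl acetate and HDM they were Mup5 7.08, 5.99, 4895 and 4.10, Gm14744 9.33, 5.53, 3746 and 4.51, and Lcn11 4.83, 5.53, 1921 and 6.97. Obp1b was 37.3, 32.7, 8156 and 34.8, 5430402E10Rik 9.65, 7.84, 1820.0 and 5.74, Gm14743 23.5, 22.6, 2022 and 22.1, and Obp1a 45.7, 45.2, 11521 and 35.3. Outside batch 2 the highest values were 0.622 for Obp1a and 0.189 for Mup5. The same 7 genes led an unnamed cluster of 343 neurons. Gm14743 and 5430402E10Rik were among the leading genes of an unnamed cluster of 139 sustentacular-type cells. Both clusters were mainly of batch 2. The neuron cluster took at most 2.67% of the cells of a mouse with water, 2.90% after soiled bedding, 2.99% after amyl acetate and 3.02% after HDM. RNA of these genes was thus not limited to gland cells or to amyl acetate, and no explanation of this pattern was tested.

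Among the class shares, 1 amyl acetate mouse held 1.66% B class cells (others 0.711% to 0.803%) and 1 soiled bedding mouse 0.492% erythroid cells (others up to 0.0824%). The macrophage class was 0.920% in 1 amyl acetate mouse (others 1.51% to 1.55%) and 0.674% in 1 water mouse (others 1.48% to 1.58%). In water mice 1 had 46.3% mature OSNs (others 30.8% to 32.1%) and 1 had 1.08% respiratory ciliated cells (others 0.295% to 0.405%). Single mice also stood apart for Coch in respiratory secretory cells after amyl acetate at 17.8 CPM, Stoml3 in neutrophils after HDM at 139 CPM, Ctxn3 in neutrophils after soiled bedding at 42.3 CPM and Fhl1 in sustentacular cells after amyl acetate at 1.90 CPM. The interferon-led cluster took 1.10% of the cells of 1 HDM mouse (others 0.174% to 0.316%). In data outside the comparisons, a cluster of neurons led by Gm42418 and Lars2 took 37.9% of the cells of the no-exposure mice and at most 0.135% in water mice.

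The first pattern is the higher share of B and erythroid cells after amyl acetate. A like rise of every blood lineage is argued against, since the median log2 fold change of the dendritic, macrophage and T, NK or innate lymphoid classes was 0.40, against 2.11 for B cells, while a smaller rise that includes neutrophils (1.02, SE 0.36, adjusted p = 0.0579) and T, NK or innate lymphoid cells (0.75, SE 0.51) stays open. Bone marrow carried over with the tissue stays open as a candidate source, since 24.69% of the B class cells held a UMI of a B cell precursor gene (median depth 3737 UMIs), against 0 of 130 T, NK or innate lymphoid cells (6469 UMIs). At 2000 UMIs per cell that share was 20.09%, and by group it was 40.91% with water, 16.67% after soiled bedding, 30.19% after amyl acetate and 15.56% after HDM. In the neutrophil class, 19.57% of the cells held a UMI of a granulocyte precursor gene (8344 CPM), against 0.42% in the B class (2.89 CPM). Of the 35 splits of the 8 mice, 2 gave as many changed classes (2 in the real split and 2 in the highest other), so chance is not excluded, and an effect of the exposure itself stays open.

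The second pattern is the higher type I interferon list in mature OSNs, a call made at the preset correlation only (adjusted p = 0.778, 0.778 and 0.896 with an estimated correlation for soiled bedding, amyl acetate and HDM). Among 35 splits an adjusted p as small came 1 time for amyl acetate (1.52e-07, smallest other 1.09e-06), 6 times for soiled bedding (8.02e-05, smallest other 4.73e-08) and 4 times for HDM (0.00831, smallest other 0.000140), so that chance is not excluded for the last 2, and the 8 splits that part all 4 batch pairs, in which the smallest other for amyl acetate was 2.46e-05, are too few for a share under 0.05. A single mouse is argued against for amyl acetate (highest adjusted p without 1 mouse 0.00241) and narrowly for soiled bedding (0.0471), while for HDM the call ended without HDM replicate 4 (0.290) and without water replicate 4. RNA of leukocytes cannot be told apart for any exposure. The 5 leukocyte genes had median log2 fold changes of -0.0832 (SD 0.484) for soiled bedding, -0.0055 (SD 0.324) for amyl acetate and -0.0198 (SD 0.349) for HDM, against 0.29, 0.50 and 0.25 for the list. Each median lay below 0.5 times the change of the list by less than the spread of the 5 genes. RNA or cells of the interferon-led cluster, if added to the support-cell RNA already present, are argued against as the whole source for soiled bedding and amyl acetate. There the rise of 20 of its abundant transcripts allows -0.0326% (SD 0.0342 over 4 pairs) and -0.0126% (SD 0.0386) of the OSN RNA, and 0.581% (SD 0.472) and 0.858% (SD 0.622) are needed. For HDM this cannot be told apart, since the spread of the share needed is wide (-0.0373% against 0.383%, SD 0.629). Many of the 20, such as Cyp2g1 and Sec14l3, are sustentacular transcripts, which need not rise if interferon-led cells replace other sustentacular cells as a source. The test cannot see that case, which stays open, as does an effect of the exposures on the neurons. The share of the cluster went with the list over the 16 mice (r = 0.735, 0.696 within batches).

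The third pattern is the lower level of neuronal genes in neutrophil-like cells after each exposure and in sustentacular cells after soiled bedding and HDM (0 genes were called there after amyl acetate), all against the same water mice. Neuronal RNA or neurons mixed into those cells stay a candidate cause, since 100% of the 17 genes called lower were at least 5 times higher in mature OSNs. Free RNA shared by every cell is argued against for neutrophils, since the genes called lower there, with medians of -4.15, -4.17 and -4.69 for soiled bedding, amyl acetate and HDM, had medians over 8 other non-neuronal classes of -0.30 (SD over classes 0.845), 0.18 (SD 0.247) and -0.16 (SD 0.491), and the mice of a batch shared their captures. These genes were picked by their fall in neutrophils, which can enlarge the fall seen there. The B cell and T, NK or innate lymphoid classes were not among the 8 classes. For sustentacular cells the test of shares cannot tell free RNA apart. By medians over mice, the per-cell median share of neuronal UMIs had log2 ratios of -0.0342 after soiled bedding and -0.0851 after HDM, against -0.37 and -0.52 for the mean share. Averaged over the 4 batch pairs, the ratios of the mean share were -0.318 (SD 0.171) and -0.366 (SD 0.475). By the medians over mice, the median share lay above 0.5 times the ratio of the mean share by 0.152 and 0.173. That is less than the spread of the margin over the 4 pairs (0.178 and 0.270). The mice of a batch shared their captures here too, so RNA free in a capture was common to the 4 exposure groups. An effect of the exposures on these cells was not tested apart from these.

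Other splits of the 8 mice of a comparison, 35 in each, were refitted for each count. In mature OSNs all 35 gave at least the 0 genes of the real split for each exposure (highest other 1 for soiled bedding, 2 for amyl acetate and 1 for HDM), and for receptors all 35 did too (1, 0 and 0). In the other cell classes 8, 13 and 7 splits gave as many genes as the real 14, 12 and 9, with highest others of 316, 132 and 243, so chance is not excluded. Such counts, many times the real ones, point to a structure of the samples, and the highest splits for soiled bedding and HDM put water replicate 2 with the exposed mice. For class shares all 35 splits gave at least the 0 classes of soiled bedding and HDM (highest others 1 and 2). For gene lists 1 split gave as many as the 16 of soiled bedding (highest other 15), while 9 gave the 14 of amyl acetate and 2 the 17 of HDM (17 in the highest other of each). Chance is not excluded for the last 2. The other splits gave medians of 10, 11 and 10 lists for soiled bedding, amyl acetate and HDM. Many lists therefore pass at the preset correlation without the real grouping of the mice. Only 8 of the splits part all 4 batch pairs as the real one does, too few for a share under 0.05, while the others keep at least 1 pair on the same side. Among the 8 splits 3, 4 and 3 gave as many genes in the other classes and 1, 4 and 1 as many lists.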

How the results depend on the processing

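The alternatives called added below, and list tests without each mouse, were chosen after seeing the data; the others were fixed before the data were examined. Of the summary results under the alternatives other than leaving out a mouse, 109 stayed within 1.5 times and 42 moved. Of the single values there (named genes of mature OSNs and 2 class shares), 415 kept their direction and side of the threshold, 3 values of class shares lost the threshold and 1 gene turned. With each mouse left out in turn, 112 summary results stayed and 24 moved. Of the single values 264 were kept, 1 lost the threshold and 7 turned. The cause was not tested where a result changed, unless one is given.

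In mature OSNs DESeq2 called 17 genes for soiled bedding, 19 for amyl acetate and 12 for HDM, where edgeR called 0. Fits of the 2 groups compared called 1 for amyl acetate, first captures 1 for HDM, second captures 1 for amyl acetate and 1 for HDM, and the marker gate 3 for amyl acetate and 4 for HDM. S100a5 after soiled bedding turned to -0.00327 with first captures. For the exposure by sex term DESeq2 called 13, 20 and 20, and first captures 1 for soiled bedding.

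In the other classes soiled bedding, amyl acetate and HDM gave 14, 12 and 9 genes. DESeq2 gave 125, 121 and 158, no low-count filter 1871, 2108 and 1715, no replicate block 54, 4 and 37, first captures 1, 4 and 1, second captures 24, 4 and 32, and the stricter cell filter 25, 3 and 52. RLE scaling gave 3 for soiled bedding, fits of the 2 groups compared 196 for soiled bedding and 20 for amyl acetate, and no cell filter 29 for soiled bedding and 41 for HDM. For HDM, at least 30 cells gave 3 and the added removal of cells with a high doublet score 4. Of the 14, 12 and 9 calls, DESeq2 kept 12, 4 and 8, RLE scaling 3, 12 and 7, no replicate block 2, 2 and 6, fits of the 2 groups compared 11, 1 and 1, first captures 0, 2 and 0, second captures 0, 3 and 2, the stricter cell filter 8, 2 and 2, at least 30 cells 11, 9 and 2, the doublet score 12, 10 and 3, and no low-count filter or no cell filter all. First captures, second captures, the stricter filter and at least 30 cells left 8, 7, 9 and 7 of the 12 classes to test, and no cell filter gave 14. The doublet score left 11, without the neutrophil class, so the neutrophil calls were not tested there. Without 1 mouse, 1 (without soiled bedding 1) to 14 (without water 2) of the 14 calls were kept, 1 (without amyl acetate 1) to 11 (without water 2 or amyl acetate 3) of the 12, and 1 (without water 1, water 4 or HDM 2) to 8 (without water 2) of the 9, and without water 1 also 2 of the 14 and 2 of the 12.

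Without the replicate block 0 classes passed after amyl acetate (B cell 2.09, erythroid 2.82, adjusted p = 0.243). First captures gave 1, with the erythroid class at 2.06 and an adjusted p of 0.243. Over all alternatives the B cell class ran from 1.82 to 2.64 (adjusted p from 0.000320 to 0.243) and the erythroid class from 2.06 to 3.69 (adjusted p from 0.00273 to 0.243). With neurons and epithelial cells as denominator 0 passed, by construction, since blood classes are not among those tested. Of the list tests 47 passed, 5 with an estimated correlation, 34 without the replicate block, and 49 with the interferon-led cluster added.

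Without 1 mouse, the other classes gave 2 to 266 genes for soiled bedding, 5 to 47 for amyl acetate and 2 to 340 for HDM, lowest without soiled bedding 1, amyl acetate 1 and HDM 3, and highest without water 2. Classes with a changed share ran from 1 (without water 4) to 3 (without water 2) for amyl acetate, 0 to 1 (without soiled bedding 2) for soiled bedding and 0 to 0 for HDM. Mature OSN genes ran from 0 to 1 (without water 2) in each comparison, the sex term from 0 to 1 (without water 1), 0 to 2 (without amyl acetate 1) and 0 to 0, receptors from 0 to 0, and list tests from 39 (without water 4) to 52 (without amyl acetate 2). S100a5 ran from -0.0425 (without water 4) to 0.0708 (without water 2) after HDM, turning also without water 1 (-0.0084), HDM 2 (-0.0128) and HDM 3 (-0.0338). It ran from -0.0248 (without water 4) to 0.0887 (without water 2) after soiled bedding and from -0.0104 (without amyl acetate 4) to 0.193 (without amyl acetate 2) after amyl acetate. mt-Cytb after amyl acetate ran from -0.0733 (without water 3) to 0.0052 (without water 4). In the neutrophil class, depth (48457 to 593769 UMIs per mouse) and a biological coefficient of variation of 0.458, against 0.0739 in sustentacular cells, both limit what is detectable, and their parts were not separated.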

Other observations

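The correlations and the descriptions in this part were chosen after the results were seen, while the test of S100a5 by receptor was chosen before its result was seen.

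S100a5, a readout of how active a neuron has been, differed widely between neurons of different receptors. Its mean log2 CPM ran from 8.42 in neurons of Olfr1507 to 16.29 in neurons of Olfr620, with an SD of 1.58 over 134 receptors. A hypothesis was that an exposure changes S100a5 only in the neurons whose receptors meet its odours. edgeR found 0 of the 134 receptors past the threshold over the 3 exposures, with 8, 13 and 8 at an unadjusted p under 0.05 for soiled bedding, amyl acetate and HDM, and a smallest adjusted p of 0.384. No other tool was run on it, and with a median SE of 0.40 only large differences in single receptors were detectable.

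Cells led by interferon-stimulated genes formed a cluster of 338 cells, whose share was 0.192% ± 0.170 (SD, n = 4) with water, 0.873% ± 1.06 after soiled bedding, 1.71% ± 1.60 after amyl acetate and 0.451% ± 0.438 after HDM. Over 16 mice the share of this cluster went with the interferon list in mature OSNs (r = 0.735, permutation p = 0.000490, adjusted p = 0.00147, Spearman rho = 0.712, 0.717 without the 2 mice farthest from the median share and 0.696 within batches, adjusted p = 0.00687 when permuted within batches). The list in mature OSNs went with that in sustentacular cells (r = 0.727, permutation p = 0.00104, adjusted p = 0.00156, rho = 0.676, 0.636 without the 2 farthest mice and 0.749 within batches, adjusted p = 0.0106 there). The share of neutrophils and that of B cells had r = 0.622 (permutation p = 0.0110, adjusted p = 0.0110, rho = 0.579, 0.375 without the 2 farthest mice and 0.486 within batches, where it did not pass, adjusted p = 0.156). These were the 3 relations examined.

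The 2 mice without exposure were a batch of their own, and a cluster of their neurons, whose best marker score was for mature OSNs (1.35), stayed unnamed and took 37.9% of their cells. Beside it they had 2.50% and 1.90% cells named mature OSNs, 11.5% and 12.0% immature OSNs, and 7.75% and 6.26% sustentacular cells. B cells made up 0.0715% and 0.634% and neutrophils 0.857% and 1.68%. Unnamed clusters took 54.0% and 53.3% of their cells.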
